A study of Homo sapiens with 3 samples.

How the data were processed

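Total RNA from 3 cultures of DLD-1 cells, 1 each at pH 7.4, pH 6.8 and pH 6.5 after 48 hours, was labelled with Cy3 and hybridised to 1 Agilent SurePrint array per culture (design 072363), per the labels and the file headers. Per the series design the medium was Opti-MEM and the acid media also received HEPES, so pH and HEPES differ together. The deposited scanner files hold a linear intensity for each spot, which the scanner software made with spatial and multiplicative detrending, per the file headers. These name Feature Extraction 10.7.1.1 with protocol GE1_107_Sep09 and probe positions on hg19, whereas the submitters' processing notes name version 9.5.1.1. The authors also deposited a value table of the same arrays, in a linear intensity. Its columns hold the same sorted values to within 0.037% and each has a median of 20.4, so it was quantile normalized across the arrays. Its values correlated with those of the matching scanner files above 0.9999 on the log2 scale. The tool that made it is not given in the sources used here.

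From the scanner files, control spots were left out, and so were 95, 109 and 120 spots that the scanner software marked as outliers on the pH 7.4, pH 6.8 and pH 6.5 arrays. Spots of the same probe were averaged, which left 58198 of 58201 probes. The processed signal was taken to log2 and each array's 75th percentile over probes was subtracted. That percentile was a signal of 321 at pH 7.4, 325 at pH 6.8 and 362 at pH 6.5. Scaled signals in the text are these values returned to a linear scale at the common 75th percentile of 335. Probes were named by their RefSeq accession through a table of GRCh38.p14 genes, used for names alone. Of the probes, 31100 were named by accession, 3369 by a current symbol and 497 by an updated older symbol, and 23235 kept the name in the file. A gene was represented by its brightest probe over the 3 arrays. Where a gene had several probes and was 2-fold different at pH 6.5, which held for 937 genes, the probes had opposite directions for 126. Genes entered a comparison when they were well above background on both arrays, by the scanner software's flag. Where a gene was well above background on 1 of the arrays and no probe of it was on the other, the difference is a bound, the bright signal against the higher of the dim signal and the lowest signal well above background on that array.

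Each of the 3 comparisons was a difference of log2 values between 2 arrays. With 1 array per pH there was no test, no p-value and no array to leave out, and genes were counted by a size rule of 2-fold. The number of arrays limits the precision. Technical error was described in 3 ways. The scanner software's signal errors gave a median error of 0.20 for a log2 difference, set mainly by a preset proportional term. Probes with 10 spots on each array had a median SD of 0.065, 0.066 and 0.060 log2 at pH 7.4, pH 6.8 and pH 6.5. Of the E1A spike-in RNAs, 8 were well above background. In processed signals before scaling they differed from the control by at most 0.061 log2 at pH 6.5. At pH 6.8 they differed by at most 0.302, and the 7 brightest by at most 0.040. None of these covers differences between cultures.

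Gene lists, 47 in number with 3 further lists of markers of other cell types, were written before the data were examined, as were the comparisons, the size rule, the main scaling, the rule for named genes and all alternatives except spike-in scaling. Of the list names, 43 were updated from older symbols and 17 had no probe. For each list the median log2 difference was placed among 10000 random lists of the same size, matched on mean signal in 20 bins. The place is a description of these arrays and no test over cultures. Lists with fewer than 3 measured members were given values only. For the comparison of both acid media, 100 sets of unchanged arrays against the same control were simulated from the scanner error alone. They gave the correlation and covariance that this error produces through a shared control, and leave out any deviation of the control culture.

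The rule named the trefoil genes, the 10 genes with a symbol that had the largest difference in each direction per comparison, the 5 largest bounds per direction, the 4 members of each list with the largest differences at each pH, or 6 for lists outside the random lists, and members 2-fold different against their list. For the comparisons with pH 7.4, the 10 largest were taken among genes with the same sign at the other acid pH. The alternatives were quantile normalization, scaling to the median of probes well above background on all 3 arrays, no scaling, normexp background correction with an offset of 50 in limma 3.58.1, only genes well above background on all 3 arrays, no filter on dim probes, the mean over all probes of a gene, the deposited value table, and a size rule that also asks for 3 errors. Scaling to the 7 brightest spike-in RNAs was chosen after seeing the data. The steps were tested on simulated data made for the comparison of pH 6.5 with pH 7.4 over 22340 genes. Of 50 genes per size, 98% were recovered at a log2 difference of 1.5 and 100% at -1.5, 2 and -2, and 0.0452% of 22140 unchanged genes passed the size rule. Of 200 random lists of 20 members, 3.5% fell outside the central 95%. The simulated arrays varied by the scanner error alone, so these shares leave out variation between cultures and give no rate of false calls between them. The random lists were drawn from the unchanged genes, so they do not stand for genes that vary together. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used.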

Results

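DLD-1 cells, an established line of human colorectal adenocarcinoma, were grown for 48 hours in medium at pH 7.4, pH 6.8 or pH 6.5, and the total RNA of each culture was measured on 1 single-colour expression array. The series title names trefoil factor 2 and acidic pH, so the first question was how the transcript of that secreted mucosal peptide differed between the media. The pH 7.4 culture was the control. Per the series design, the acid media also received HEPES buffer, so acidity and HEPES differed together between the control and the acid media. Each array held 60901 non-control spots. The share of probes well above background was 53.3% at pH 7.4, 52.7% at pH 6.8 and 54.1% at pH 6.5, and no spot was saturated. With 1 array per pH, no difference below has a replicate check. The errors given are those that the scanner software attached to the signals, about 0.20 on the log2 scale for most differences. They come mainly from a preset proportional term and do not cover variation between cultures.

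TFF2, which encodes trefoil factor 2, a peptide secreted with mucus by gastric epithelium, had a scaled signal of 56.1 at pH 7.4, 88.4 at pH 6.8 and 1018 at pH 6.5. The pH 6.5 signal was 18.1-fold that of the control, a log2 difference of 4.18 with an error of 0.22, and TFF2 ranked 27 from the top among 22748 genes measured on both arrays. At pH 6.8 the log2 difference was 0.66 with an error of 0.23, a 1.58-fold higher signal and rank 788 among 22871 genes. Between the acid media the pH 6.5 signal was 11.5-fold higher. With normexp background correction, which pulls dim signals together, the TFF2 log2 difference was 3.16 at pH 6.5 and 0.34 at pH 6.8. TFF2 was read by a single probe, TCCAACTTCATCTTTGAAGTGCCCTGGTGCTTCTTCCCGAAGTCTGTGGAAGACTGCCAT, whose 60 bases the design file places on the minus strand of chromosome 21 between 43766648 and 43767646 of hg19.

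The other trefoil genes did not share this difference. TFF1, the trefoil peptide of gastric surface cells, had log2 differences of -0.01 at pH 6.5 and -0.12 at pH 6.8, both within the scanner error, and the sign at pH 6.5 turned with quantile normalization or without scaling. TFF3, the trefoil peptide of goblet cells, was already bright in the control, with a scaled signal of 19520 at its brightest probe. That probe gave -0.71 at pH 6.5 and -0.20 at pH 6.8. The 3 probes of TFF3 disagreed in direction at pH 6.5, with log2 differences of -0.71, -0.60 and 0.54, so no direction is given for TFF3.

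**Figure D1:**
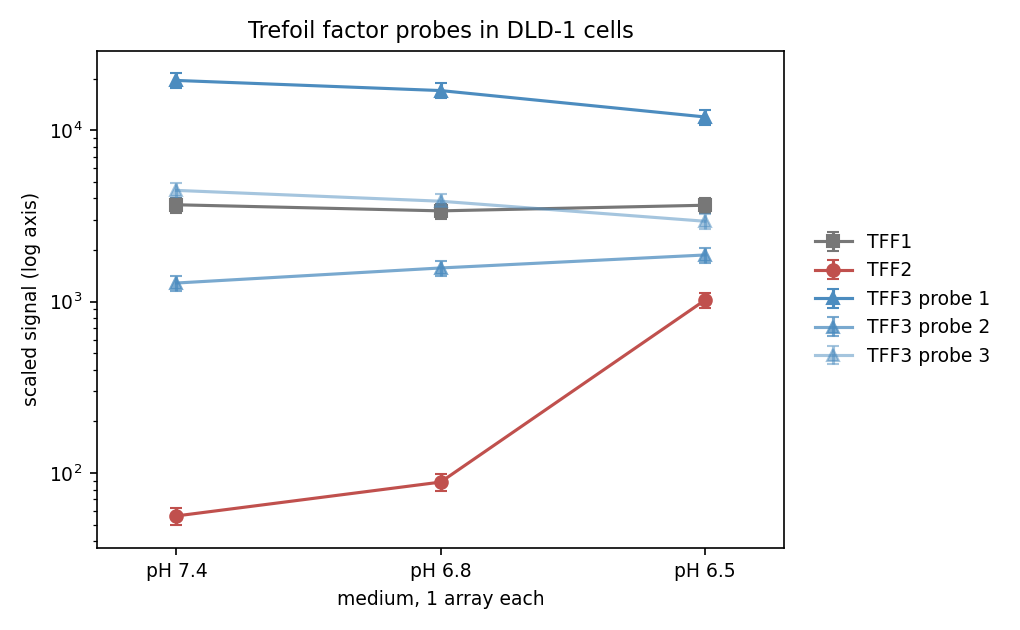
Scaled signal (log axis) of each trefoil factor probe on the pH 7.4, pH 6.8 and pH 6.5 arrays, 1 array each; bars are the scanner software's signal errors. TFF2 goes from 56.1 at pH 7.4 to 1018 at pH 6.5, while the single TFF1 probe stays near its control level and the 3 TFF3 probes go in both directions.

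At pH 6.5, genes of DNA replication and mitosis were much lower than in the control, and single genes such as UCA1, CCL26 and SLC5A3 were much higher. The largest positive difference among genes well above background on both arrays was that of UCA1, a long non-coding RNA, at 8.30 on the log2 scale, from a scaled signal of 203 to 64048. It was followed by the chemokine gene CCL26 at 6.67, the cytochrome P450 gene CYP3A7 at 6.28, the death-receptor caspase gene CASP10 at 5.81, the cystatin gene CST2 at 5.63 and WFDC21P at 5.60. CYP3A7 and CST2 have near-identical relatives, so which copy was read is uncertain. SLC5A3, the sodium-coupled myo-inositol transporter, was higher by 5.51, SPINK1, a secreted trypsin inhibitor, by 5.50, S100A3 by 5.44 and the water and glycerol channel AQP3 by 5.23. Some genes were well above background at pH 6.5 but not at pH 7.4, and among these the betaine and GABA transporter gene SLC6A12 was higher by at least 8.61, PRSS35 by at least 7.35 and CALB1, encoding the calcium-binding protein calbindin, by at least 7.29. The most negative differences among genes measured on both arrays were those of the histone genes H3C15 (-5.10), H2AC16 (-4.85), H1-5 (-4.79) and H2AC13 (-4.29), the transcription factor gene MYB (-4.54) and the replication genes MCM10 (-4.35), GINS2 (-4.28) and RRM2 (-4.22). SNAR-F (-4.16) and FAM111B (-4.13) completed that group. Of genes well above background at pH 7.4 but not at pH 6.5, the hedgehog-binding protein gene HHIP had a log2 difference of -3.94 or further from 0 and DNAJA4, a co-chaperone gene, of -3.76 or further.

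In all, 1849 genes were 2-fold or more higher at pH 6.5 than at pH 7.4 and 2175 were 2-fold or more lower, of 22748 genes measured on both arrays. Differences of at least 4-fold were found for 434 genes in the higher and 421 in the lower direction, and of at least 8-fold for 105 and 81. A further 498 genes were 2-fold or more higher and 279 lower by their bounds. The higher genes were dim in the control, with a median scaled signal of 143, against 869 for the lower genes and 415 for all. This contrast is partly built in, since genes were picked by their difference from that same control signal. The split between the directions depended on the scaling. Higher genes made up 45.9% of the genes past 2-fold, 60.3% without scaling and 61.1% with scaling to spike-in RNAs, which moved the median log2 difference of all genes from -0.07 to 0.10 and 0.11. Normexp correction left 1151 higher and 1425 lower genes, and keeping dim probes gave 3726 and 4403.

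DNA replication genes had a median log2 difference of -2.35 at pH 6.5, and 38 of the 42 measured members were 2-fold or more lower. Besides MCM10, GINS2 and RRM2 these included the helicase cofactor gene CDC45 (-3.66), the thymidylate synthase gene TYMS (-3.43) and MCM5 (-3.18). Mitosis genes had a median of -2.32, with 37 of 40 at least 2-fold lower. HMMR stood at -3.71, the ubiquitin-conjugating enzyme gene UBE2C at -3.02, the survivin gene BIRC5 at -3.01, the Aurora kinase gene AURKB at -2.96 and the cyclin gene CCNA2 at -2.90. For both lists the median lay below all 10000 random lists of matched size and signal. Histone genes had a median of -1.35, with 13 of 22 members at least 2-fold lower and 3 at least 2-fold higher. Histone genes are near-identical to each other, so the values of single members are uncertain. The list of MYC targets and ribosome biogenesis had a median of -1.11, with 19 of 32 members at least 2-fold lower and none higher. Its lowest values were those of RRS1 (-2.49), the nucleolar protein gene NOP56 (-2.12) and the ornithine decarboxylase gene ODC1 (-2.07).

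Stem cell and Wnt target genes of the intestine had a median of -0.76, and 6 of 15 were at least 2-fold lower. They included ASCL2 (-2.63) and LGR5 (-1.91), markers of intestinal stem cells, LEF1 (-1.55) and MYC (-1.12). Genes of glutamine, serine and one-carbon metabolism had a median of -0.59, with 8 of 25 at least 2-fold lower, and 2 members at least 2-fold higher, among them the glutamine transporter gene SLC38A2 (2.13). These 6 lists were the ones whose medians lay below the central 95% of random lists. The brightest probe of RRM2 differed from its others, and the mean over its probes was -2.25. For H2AC11 (-4.13) that mean was -2.16.

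Lists above the central 95% of random lists at pH 6.5 numbered 15 of 47. Extracellular proteases and their inhibitors had the highest median, 0.89, and 9 of 21 members were at least 2-fold higher. The metalloproteinase inhibitor gene TIMP3 was higher by 4.92, the tissue plasminogen activator gene PLAT by 3.23, SERPINB5 by 1.96, MMP14 by 1.68 and the urokinase gene PLAU by 1.57. Steroid and xenobiotic metabolism had a median of 0.70, with 5 of 13 members at least 2-fold higher. Among them were CYP1A1 at 4.34, AHRR at 2.16 and CYP1B1 at 1.67, which are induced through the aryl hydrocarbon receptor, and UGT2B7 at 2.79, whose close relatives make the copy uncertain. Cholesterol efflux genes had a median of 0.62, with ABCG1 at 2.28 and APOE at 2.04. Mesenchymal transition genes had a median of 0.57 (4 of 16 at least 2-fold higher), with S100A4 at 2.66, SPARC at 2.25 and TGFB1 at 1.98, while the vimentin gene VIM stood at -0.93. TGF-beta and BMP targets had a median of 0.49, with SMAD6 at 2.35 and BAMBI at 1.82, against ID1 at -1.41.

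NF-kB targets and inflammatory mediators had a median of 0.47 and went both ways, with 7 of 28 members at least 2-fold higher and 4 at least 2-fold lower. The cytokine gene CSF2 was higher by 3.41, the NF-kB inhibitor gene NFKBIA by 2.37, TNFAIP2 by 2.34 and PTGS2, encoding cyclooxygenase-2, by 2.27. The iron-binding lipocalin gene LCN2 (-3.82) and the neutrophil chemokine genes CXCL2 (-2.95), CXCL3 (-2.27) and CXCL8 (-1.13) were lower. Autophagy genes had a median of 0.45, with 7 of 29 members at least 2-fold higher and none lower, among them the initiating kinase gene ULK1 at 1.59 and the cargo receptor gene OPTN at 1.23. Mucins and gastric-type genes had a median of 0.45, with 3 of 12 at least 2-fold higher. The cell-surface mucin genes MUC1 and MUC13 stood at 2.19 and 1.71 and GAST at 1.15. Lysosome genes had a median of 0.40, with the protease gene CTSF at 3.45 and the sialidase gene NEU1 at 2.49, against CTSC at -1.64. Interferon-stimulated genes had a median of 0.37, with 7 of 29 members at least 2-fold higher (OASL 2.76, IRF9 1.56) and 2 at least 2-fold lower. Acid-sensing receptors and channels had a median of 0.35, with the acid-gated channel gene ASIC3 at 2.31 and the potassium channel gene KCNK1 at 1.87. V-ATPase subunits and immediate early genes both had medians of 0.33, the latter with 6 of 28 members at least 2-fold higher and 5 at least 2-fold lower, epithelial junction and keratin genes of 0.30 and antigen presentation genes of 0.25.

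Several lists moved inside the random lists or had medians closer to 0 under other processing, and the cause was not tested. Mucins and gastric-type genes lay inside the central 95% when all probes of a gene were averaged or only genes well above background on all 3 arrays were used, and acid-sensing and antigen presentation genes did so with normexp correction. When dim probes were kept, the interferon, TGF-beta and cholesterol efflux lists lay inside, and antigen presentation had a median of -0.06, while stem cell and Wnt targets had one of -0.44. Normexp correction brought the medians of mesenchymal transition genes to 0.27, of autophagy genes to 0.26, of NF-kB targets to 0.25 and of acid-sensing genes to 0.13. With normexp correction the difference of CTSF at pH 6.5 was 1.57, of SPARC 0.96, of OASL 1.40, of CSF2 2.07, of TNFAIP2 1.32, of PTGS2 1.31, of MMP14 1.11, of GAST 0.56, of LGR5 -1.09, of WFDC21P 3.41 and of CYP3A7 4.06. The mean over the probes of CASP10 was 2.59.

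The other 26 lists lay inside the central 95% at pH 6.5, though in most of them single members differed by 2-fold or more. No member did so among ribosomal proteins, metallothioneins and zinc transport, or enteroendocrine markers. Median log2 differences were 0.39 for cyclin-dependent kinase inhibitors (CDKN1C 2.14, CDKN3 -3.17), 0.28 for YAP and TEAD targets (ANKRD1 3.18), 0.18 for hypoxia targets (ANGPTL4 2.76, NDRG1 1.47), 0.13 for fatty acid oxidation and lipid storage (PPARA 2.54, FABP5 -2.16) and 0.11 for apoptosis regulators (BMF 3.17). They were 0.08 for p53 targets (TP53INP1 2.98), goblet and secretory markers (AGR2 -1.54) and growth factors and receptors of the EGF family (EGF 1.72), and 0.02 for metallothioneins and zinc transport. Of the 11 goblet and secretory markers measured, 2 were at least 2-fold higher, SPINK1 among them, and 3 were at least 2-fold lower. Normexp correction brought ANKRD1 to 1.99, TP53INP1 to 1.86 and EGF to 0.44, and the mean over the probes of PPARA was 1.60. When dim probes were kept, the medians of fatty acid oxidation and of metallothioneins turned to -0.07 and -0.09. The medians of 9 lists near 0 turned sign under another scaling. These were trefoil factors (-0.01), cholesterol biosynthesis (-0.03), acid-base transporters and carbonic anhydrases (-0.04), heat shock genes (-0.05), enterocyte and colonocyte markers (-0.06), iron handling (-0.09), NRF2 and oxidative stress genes (-0.12), enteroendocrine markers (-0.12) and fatty acid synthesis (-0.16). Medians were -0.20 for MondoA and ChREBP targets, -0.26 for glycolysis (ALDOC 3.03, ENO1 -1.26) and for the TCA cycle, -0.29 for the integrated stress response (CTH 2.70, SLC7A11 -1.27), -0.32 for oxidative phosphorylation and -0.34 for endoplasmic reticulum chaperones. Ribosomal proteins stood at -0.41 and housekeeping reference genes at -0.34, with HPRT1 at -1.59. Quantile normalization brought ribosomal proteins to -0.07, oxidative phosphorylation to -0.06, glycolysis to -0.03, the TCA cycle to -0.02 and housekeeping genes to -0.12.

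Markers of other cell types were scarce. Of fibroblast markers only PDGFRB and FAP were measured, and PDGFRB was dim, with scaled signals of 16.1, 48.5 and 82.5 from pH 7.4 to pH 6.5 and a log2 difference of 2.36 at pH 6.5, or 0.76 with normexp correction. Of leukocyte markers 5 were measured at pH 6.5, with a median of 0.65 at the 98.1 percentile of random lists (CSF1R 1.12, CD2 0.96). With normexp correction CD2 and the list median were 0.22, and the list lay inside the central 95% when dim probes were kept or all probes of a gene averaged, and 3 endothelial markers had a median of 0.01, a sign that turned with quantile normalization.

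**Figure D2:**
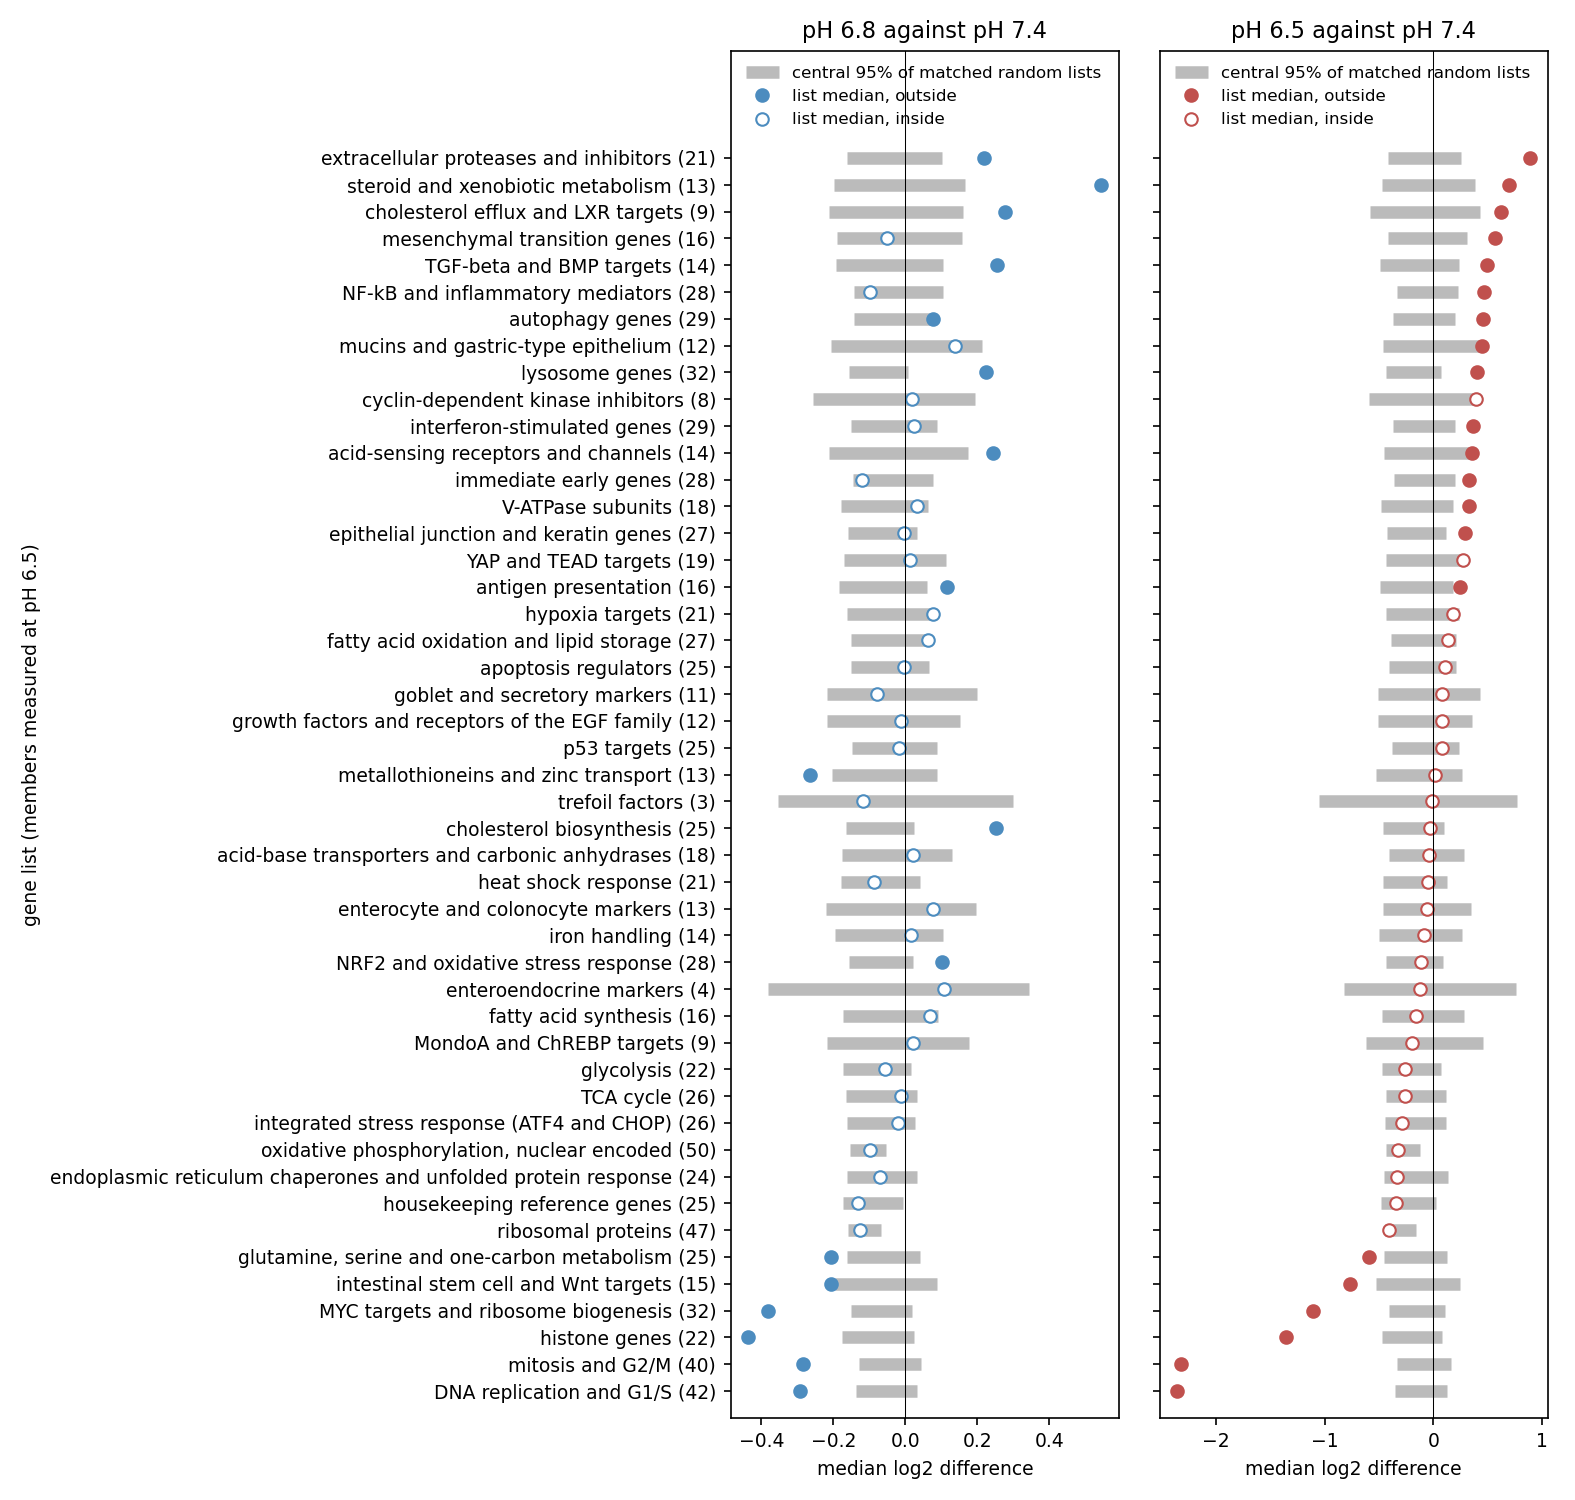
Median log2 difference of each of 47 gene lists at pH 6.8 (left) and pH 6.5 (right) against pH 7.4, 1 array each; grey bars are the central 95% of 10000 random lists of the same size and signal, and filled points lie outside them. DNA replication (-2.35) and mitosis (-2.32) lie farthest from the random lists at pH 6.5; the 2 panels have different axis ranges.

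**Figure D3:**
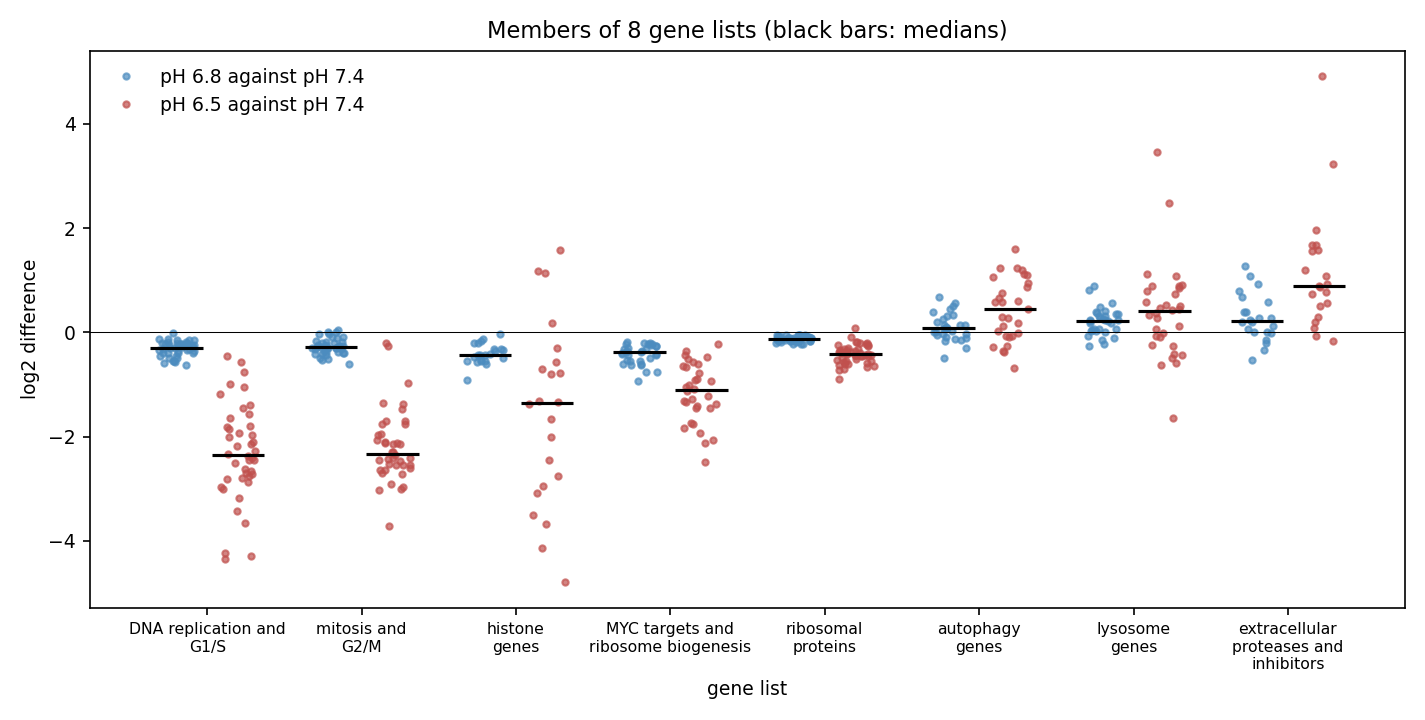
Log2 difference against pH 7.4 of each measured member (points) of 8 gene lists at pH 6.8 and pH 6.5, with list medians as black bars. Replication and mitosis genes have medians of -0.29 at pH 6.8 and of -2.35 and -2.32 at pH 6.5, while ribosomal proteins stay near -0.13 and -0.41.

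At pH 6.8 the differences were fewer and smaller. UCA1 was again the highest named gene, at 2.91, followed by PALM3 at 2.56, the cadherin gene CDH13 at 2.45, the hyaluronidase gene HYAL1 at 2.31, the potassium channel subunit gene KCNAB2 at 2.28 and QPRT, an enzyme of NAD synthesis, at 2.10. BCAS1, TMEM63C, CLIP2 and SH2D3C stood between 2.01 and 1.84. The lowest named gene was CXCL8, encoding the neutrophil chemokine interleukin-8, at -2.11. The small non-coding RNA genes SNAR-F (-1.94), SNAR-D (-1.84), SNAR-G2 (-1.82), SNAR-A3 (-1.66) and SNAR-B2 (-1.62) were also among the 10 lowest, though their near-identical sequences make single values uncertain. HHIP stood at -1.60 and GDAP1, a mitochondrial protein gene, at -1.57.

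In all, 196 genes were 2-fold or more higher and 139 lower at pH 6.8, of 22871 measured on both arrays, and 8 and 1 of them reached 4-fold. By bounds, 91 more were higher and 72 lower. These genes were dim, with median control signals of 46.3 for the higher and 74.0 for the lower ones, and their number depended on how dim signals were treated. Normexp correction left 46 higher and 15 lower genes, which moved the higher share from 58.5% to 75.4%, while keeping dim probes gave 1689 and 1598. With normexp correction CDH13 stood at 0.98, HYAL1 at 1.05, KCNAB2 at 0.97, SH2D3C at 0.62, GDAP1 at -0.61, HHIP at -0.91 and TIMP3 at 0.55 at pH 6.8.

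Growth-related lists were lower at pH 6.8 by small amounts that almost all members shared. Histone genes had a median of -0.44 with all 22 members below 0, MYC targets and ribosome biogenesis of -0.38 with all 32 below 0, DNA replication of -0.29 with all 42 below 0 and mitosis of -0.29 with 37 of 40 below 0. None of these members reached 2-fold. Among them were H2AX (-0.92), ODC1 (-0.92), RRS1 (-0.76), NOP56 (-0.76), ORC1 (-0.63), which marks replication origins, and the kinetochore gene CENPF (-0.60). Ribosomal proteins also had all 47 members below 0, with a median of -0.13 that lay inside the random lists. The counts below 0 alone therefore do not set the growth-related lists apart. Small medians also depended on the scaling, and quantile normalization moved that of housekeeping reference genes from -0.13 to 0.01. Metallothioneins and zinc transport had a median of -0.26, with the metal-binding proteins MT1M at -0.94, MT1E at -0.89 and MT1X at -0.81, and stem cell and Wnt targets and one-carbon metabolism both had medians of -0.21.

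Lists above the random lists at pH 6.8 numbered 10. Steroid and xenobiotic metabolism had the highest median, 0.55, with 11 of 13 members above 0 and CYP1A1 at 0.87. With normexp correction the list median and CYP1A1 were both 0.35 and ASIC3 was 0.52. Cholesterol efflux genes had a median of 0.28, and cholesterol biosynthesis genes of 0.25, with 21 of 25 above 0. The latter included the sterol oxidase gene MSMO1 at 0.66 and INSIG1 at 0.63. TGF-beta and BMP targets had a median of 0.25 (SMAD6 1.53), acid-sensing genes of 0.24 (ASIC3 0.87), lysosome genes of 0.23 with 27 of 32 above 0, and extracellular proteases of 0.22 (SERPINB5 1.27, TIMP3 1.08). Antigen presentation genes stood at 0.12, NRF2 targets at 0.10 (AKR1C3 1.45 and AKR1C1 1.13, near-identical copies) and autophagy genes at 0.08. One-carbon metabolism lay inside the random lists with quantile normalization, and stem cell and Wnt targets did so with normexp correction.

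Between the acid media, replication and histone genes were again among the lowest at pH 6.5. Relative to pH 6.8, PRSS35 was higher by 6.58, CCL26 by 6.55, CYP3A7 by 6.11, the cystatin gene CST1 by 5.70, UCA1 by 5.39, SPINK1 by 5.37 and SLC5A3 by 4.88. H3C15 (-4.60), H1-5 (-4.19), MYB (-4.06), MCM10 (-4.02) and DTL (-3.65), a ubiquitin ligase subunit of S phase, were the lowest along with other histone and replication genes. CST1 and CST2 encode near-identical cystatins, so their separate values are uncertain. Mitosis genes had a median of -2.04 and DNA replication genes of -1.92, each with 37 members at least 2-fold lower. Lists above the random lists numbered 13 and lists below 7, while acid-sensing genes, TGF-beta and BMP targets, steroid and xenobiotic metabolism, antigen presentation and mucins lay inside. Metallothioneins and zinc transport had a median of 0.27 between the acid media, and immediate early genes of 0.33 with 7 of 28 at least 2-fold higher and none lower. NF-kB targets and inflammatory mediators had a median of 0.56. In all, 1308 genes were 2-fold or more higher and 1426 lower at pH 6.5 than at pH 6.8, of 22736. Higher genes made up 47.8% of these, 63.9% without scaling, and normexp correction left 760 higher and 901 lower.

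Across the 22340 genes measured on all 3 arrays, the differences at pH 6.5 and pH 6.8 correlated with a Pearson r of 0.60 and a Spearman rho of 0.61, over genes, which are not independent replicates. Both differences use the same control array, and simulated unchanged arrays that varied by scanner error alone gave r = 0.50 against it. Arrays of like error give such a value by construction, so it is no baseline for arrays that spread unlike. The covariance was 0.179, against 0.026 in the simulation, a difference of 0.154. The simulation leaves out any deviation of the control culture itself, so this difference is no measure of a shared response. Of the genes 2-fold or more higher, 146 were shared by both acid media, where independent lists of those sizes would share 15.8, and 66 of the lower genes were shared, against 11.2. The control array could not be split, so part of this excess may come from the shared control. UCA1, PALM3, HYAL1, CDH13 and SERPINB5 were among the higher genes of both media, and SNAR-F, SNAR-D and CXCL8 among the lower. The slope of the pH 6.8 differences on those at pH 6.5 was 0.24. Genes whose pH 6.8 value lay between the other values made up 58.2% (95% Wilson interval 57.5 to 58.8), where exchangeable values would give 33.3%. Genes are not independent, so that interval covers counting error only. Exchangeable values also need arrays that spread alike. The SD of the differences across genes was 0.86 for pH 6.5 against pH 7.4 and 0.72 for pH 6.5 against pH 6.8. For pH 6.8 against pH 7.4 it was 0.35. A pH 6.5 array that stands apart would by itself raise the share above 33.3%, so the excess does not show a graded effect. The share was 86.3% among genes 2-fold higher at pH 6.5 and 92.9% among those 2-fold lower, groups picked for a wide gap between the end values.

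**Figure D4:**
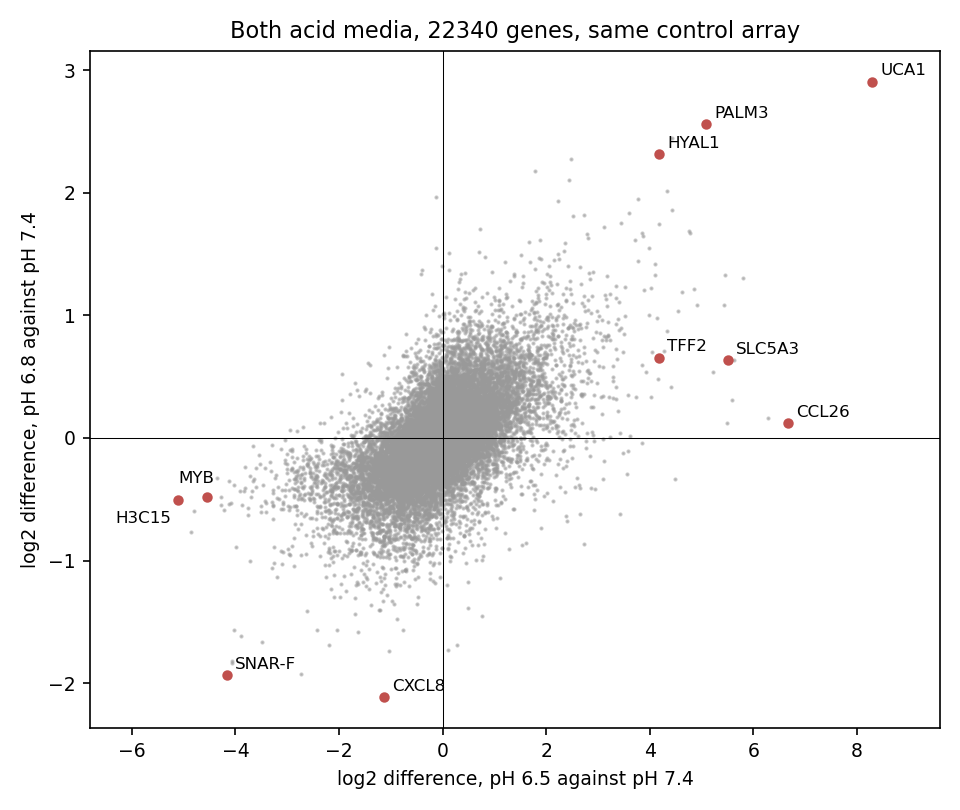
Log2 difference of each of 22340 genes (grey points) at pH 6.5 (horizontal) and pH 6.8 (vertical) against the same pH 7.4 array, with named genes in red; the axes have different ranges. The cloud has r = 0.60, with UCA1 highest of the named genes on both axes, CCL26 at 6.67 with little difference at pH 6.8, and CXCL8 lowest at pH 6.8 (-2.11).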

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

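FLJ13744, a transcript outside the rule for named genes and chosen after its values were seen, was the only gene of the 22340 measured on all 3 arrays that differed by 2-fold or more in opposite directions in the acid media. Its log2 difference against pH 7.4 was 1.12 (error 0.21) at pH 6.5 and -1.14 (error 0.24) at pH 6.8. The difference between these values was not tested, since each pH had 1 array.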

How the results depend on the processing

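Each pH had 1 array, so no leave-one-out run was possible. No paired analysis was possible because each pH has 1 array. Differences of dim genes are limited by how far their signal lies over background. Of the main results under the alternatives, 93 stayed the same and 21 moved, and the cause was not tested for any. Some of the 93 could not move. A constant shift of whole arrays leaves the correlation unchanged, so median, spike-in and no scaling all gave 0.603. TFF2 has a single probe, so neither the filters on dim probes nor the mean over probes could change its value. Nearly all genes past 2-fold also pass 3 errors, because the median error is 0.20. With normexp background correction, 1151 genes were 2-fold higher and 1425 lower at pH 6.5 than at pH 7.4, 46 and 15 at pH 6.8 than at pH 7.4, and 760 and 901 at pH 6.5 than at pH 6.8. The TFF2 difference was 3.16 at pH 6.5 and 0.34 at pH 6.8, and the correlation between the acid media was 0.642. Without the filter on dim probes the counts were 3726 and 4403, 1689 and 1598, and 3046 and 3467. The correlation was then 0.485, 45.5% of genes were ordered with pH, and the antigen presentation list at pH 6.5 reversed to -0.0592. Quantile normalization gave a correlation of 0.594 and 57.2% ordered, and the values that the authors deposited gave 0.593 and 57.2%. Scaling to spike-in RNAs, chosen after seeing the data, kept each count within 1.5 times, the limit set for counts, but turned the majority at pH 6.5 against pH 7.4, with 2494 genes higher and 1588 lower. Over named genes 4199 values stayed the same and 309 moved, 137 of them with normexp correction. Of the same values, 501 without the dim filter and 500 with the filter on all 3 arrays were fixed in advance. A filter does not change a gene's value. Over lists 857 stayed the same, 12 were stronger, 12 weaker and 1 reversed. A constant shift cannot change the place of a list among random lists. Median, spike-in and no scaling therefore gave 98 same results each largely by construction.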

Other observations

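Beyond the lists fixed in advance, 457 gene families that share a symbol stem and have at least 5 measured members were scanned at pH 6.5, a scan chosen after the data were seen. Of these, 63 had medians above the central 95% of matched random lists and 43 below, where 11.4 would fall on each side if families behaved as random lists. The cell division genes of the CDCA stem had a median log2 difference of -2.80 with all 7 at least 2-fold lower, and 7 of 8 alpha-tubulin genes were at least 2-fold lower (TUBA1B -2.14), although tubulin copies are alike in sequence. Mitochondrial ribosomal proteins of the MRPL stem had a median of -0.62 over 49 genes (MRPL15 -1.63, MRPL24 -1.57), the GEMIN genes of snRNP assembly of -1.44, and the TIMM genes of mitochondrial protein import of -0.68, with TIMM10 at -2.56 and TIMM8B at -2.18.

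Families in the other direction included the semaphorins, guidance and signalling proteins, with a median of 0.99 over 15 genes (SEMA5A 3.98, SEMA4G 2.53, SEMA3A -1.44), and the STAT transcription factors, with a median of 0.98 and all 7 above 0 (STAT5A 1.72, STAT3 1.14). The RAB stem, mostly small GTPases of vesicle traffic, had a median of 0.33 over 60 genes (RAB17 2.28, RAB3B 2.26, RAB14 -1.63). Collagen genes had a median of 0.61 over 22 genes, or 0.11 with normexp correction, and divided, with COL13A1 at 4.79, COL6A1 at 2.98 and COL7A1 at 2.54 against COL4A2 at -1.41 and COL4A1 at -0.98. YPEL3 and YPEL2 stood at 3.04 and 2.66. Each family median named here kept its sign under every scaling and background correction that was run.

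In the weighing of the next 3 patterns, the tests of the osmotic gene list and of all other short RNAs were set before their results were seen, and the other tests were chosen after.

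The first pattern is the lower level of the cell cycle genes at pH 6.5, 82 genes of replication and mitosis with a median of -2.34 and 75 at least 2-fold lower. Array scaling is argued against as the whole cause, because the scaling with the weakest result still gave a median of -2.15. So is hybridization or scanning error, because none of the 8 E1A spike-in RNAs well above background differed by more than 0.061 before scaling. However, dim ERCC control probes well above background on all 3 arrays differed by up to -0.72. A graded effect of the acid media stays open. Of these genes 96.3% were ordered from pH 7.4 over 6.8 to 6.5, but so were 92.9% of all genes 2-fold lower at pH 6.5, a group picked for a wide gap. The state of a single culture, such as its density or nutrient supply, could not be separated from pH, because there was 1 array per pH.

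The second pattern is the higher level of osmolyte transporters at pH 6.5, where SLC5A3 was higher by 5.51 and SLC6A12 by at least 8.61. A single faulty probe stays open for each gene, since each has 1 probe. An osmotic response through NFAT5, the transcription factor of hypertonic stress, was tested on 14 other genes listed before their joint median was computed, 4 of which had already been measured in other lists. The 13 measured genes had a median of 1.31 at pH 6.5, the 100 percentile of matched random lists, with 8 at least 2-fold higher (AKR1B1 1.41, NFAT5 1.31, S100A4 2.66) and HSPA4L at -1.12, and a median of 0.25 at pH 6.8; without those 4 genes the median was 0.71 at pH 6.5, the 99.7 percentile. The added HEPES may have raised the osmolality of the acid media, but osmolality was not analysed here and pH and HEPES differ together, so this stays a hypothesis. The pH 6.8 medium also received HEPES, yet SLC5A3 was higher by only 0.63 there and SLC6A12 was not well above background.

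The third pattern is the lower level of SNAR RNAs in both acid media, with medians over 10 genes of -1.59 at pH 6.8 and -3.69 at pH 6.5. The larger differences lay in the 7 genes whose probes are alike, while SNAR-C4, SNAR-E and SNAR-I stood at -0.44, -0.41 and -0.76 at pH 6.8 and at -0.61, -0.78 and -1.01 at pH 6.5. Poorer recovery or labelling of short RNAs could contribute, although over 228 other RNA genes under 200 bases the median was -0.18 at pH 6.8, which by the limit set beforehand argued against it. That reading was changed to open after the values were seen, because 207 of these are snoRNA genes, while the 21 of other classes had a median of -0.49 with 19 below 0, and at pH 6.5 the medians were -0.38 over 227 genes and -1.35 over the 20 of other classes. Of the other classes the rRNA gene RNA5-8SN5 went the other way, higher by 1.29 at pH 6.8 and by 2.84 at pH 6.5. The 7 SNAR probes that share 15 or more bases with another SNAR probe ranged over 1.01 at pH 6.8 and over 2.60 at pH 6.5, where the dim SNAR-G1 stood at -1.57 and the other 6 between -3.49 and -4.16, so for these 6 separate copies and a shared signal cannot be told apart.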
